A study of Homo sapiens with 4 samples.

How the data were processed

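Guides were sequenced from genomic DNA of HCT116 reporter cells. Per the labels, 19000000 cells were seeded into each of 7 dishes per replicate, transduced in 8 µg/mL polybrene with virus for about 0.5 infections per cell, and kept in 1 µg/mL puromycin for 10 days before the dimmest 0.5% were sorted. Per the labels' protocols, guides were amplified in 18 cycles of PCR, in 40 reactions of 6.6 µg DNA for unsorted cells and in 2 reactions of all recovered DNA for sorted cells, and then in 13 to 14 further cycles. DNA was also extracted by different methods from sorted and unsorted cells, so extraction and input differ together with the sort. No molecular identifiers were used in the values, so reads are not independent molecules.

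The deposited values are a normalized signal per guide, made by the authors as reads per 1000000 reads (RPM) plus 1. The lowest value in each library was exactly 1, and the values less 1 summed to 1000000 in each. The submitters' processing notes name bcl2fastq, MAGeCK and the build hg38. Versions, the aligner and the settings are not given in the sources used here. The values less 1 were whole multiples of 1 step per library (100% within 0.01 reads), and the total reads and median reads per guide in the text come from that step. Since the authors' added constant stands in the values as deposited, they were treated as a normalized signal and tested on a log scale.

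Libraries were grouped as dim and unsorted by their titles, with reporter clone 1 as replicate 1 and clone 2 as replicate 2 of each group. The labels name the clones as independent biological replicates. Of 77441 guides, 1000 were non-targeting. Values were put on the log2(value + 1) scale, where the pseudocount is 10% of the median unsorted value (11.5) rounded to 1 significant digit. A fold change on this scale understates the change of guides with low values. Guides whose mean over the 4 libraries was below 1.15, again 10% of that median, were left out (350), and 77091 remained. Both settings count the authors' added 1 as part of the value. The filter therefore took out only guides close to the lowest possible value, and a pseudocount of 0 still leaves that 1 in place. Each guide was compared between dim and unsorted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided). The log2 ratio of a gene is the mean over its guides, computed within each clone against the unsorted library of that clone, and the SD is over the 2 clones.

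Genes were scored by alpha-RRA, the kind of gene score MAGeCK gives. Guides were ranked by the one-sided limma statistic, guides with a one-sided p under 0.25 set the share of ranks considered, and p came from 5000000 random draws for each number of guides, with Benjamini-Hochberg adjustment in each direction at 0.05. Genes with at least 2 guides entered (19107 genes, 18762 of them with 4). The table held 26 gene names turned into dates, and 2 of those, with 8 guides each, stood for more than 1 gene and were left out. A second test used limma on each gene's mean over guides per library, with 2 against 2 libraries. Gene lists were tested with limma camera at a preset correlation of 0.01, with estimated-correlation and fry versions beside it, and members were also adjusted over the list alone. That adjustment was made in each list and direction separately, without correction across the 30 lists. Symbols were matched to the GENCODE release 44 annotation of hg38: of 19107 symbols, 17850 were current, 1109 were updated through older names and 148 had no match. Coordinates are of the whole gene on hg38. The positions of single guides were not used here.

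The rule for named genes was fixed before the data were examined. It took the 25 genes with the smallest alpha-RRA p toward dim among those past 0.05 and positive in both clones, the same in the other direction or the 3 smallest as values if none passed, up to 4 members per list that passed over all genes or over the list alone, the 4 NXF1-TREX genes with the smallest p that did not pass, genes past the gene-level limma test, and always a few genes set in advance, among them PUM2, RBMX, NXF1 and XPO1. Some genes that the rule takes are not reported here. Intervals of shares are 95% Wilson intervals.

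The clone numbers pair the samples because each clone is a reporter line of its own. Checked on the data, the deviations of dim replicate 1 and unsorted replicate 1 from their group means correlated at 0.087 over guides, a value that would be the same for the other clone. With clone as a block, limma estimated a common variance for all genes, so the blocked p rest on pooled spread.

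Alternatives covered the pseudocount, the filter, rescaling and centring on non-targeting guides, the clone block, leaving out each library, other guide rankings, a null from non-targeting guides, the threshold, the median over guides, and other list tests. A pseudocount of 0 and limma voom on the recovered reads were added after seeing the data. The planned count tests were not run.

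The steps were tested on simulated data for the comparison of dim with unsorted, with guide shares from the unsorted libraries, the real totals, 200000 sorted cells drawn at random per clone and 200 genes changed, run on 19107 genes. Alpha-RRA called 14.9% of 67 genes changed 2-fold, 88.1% of 67 changed 4-fold and 100% of 66 changed 8-fold, with 2 false calls toward dim and 0 toward depletion among 18907 unchanged genes. Gene-level limma called 2.99%, 28.4% and 78.8% with 0 false calls, and with the clone block 17.9%, 94.0% and 100% with 83 false calls. All guides of a changed gene got the same fold in both clones, and only increases were simulated. Guides of real genes differed (0.50 to 4.66 for PTBP1), so the rates may be too high for them. Detection of depletion was not covered. The median log2 ratio of unchanged genes in the simulation was -0.31. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.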

Results

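The screen asked which protein-coding genes are needed for expression of a reporter built on NORAD, a long noncoding RNA that works in the cytoplasm, with the stated aim of finding factors that export it from the nucleus. HCT116 cells, an established colon cancer line, carried a NORAD-IRES-GFP reporter, in which an internal ribosome entry site (IRES) lets the GFP be translated from the NORAD transcript. The cells received the Brunello CRISPR knockout library, in which each gene is cut by about 4 guide RNAs. In each of 2 independently derived reporter clones, the dimmest 0.5% of cells by GFP (at least 200000 cells) and 50000000 unsorted cells were sequenced for their guides, giving 2 dim and 2 unsorted libraries. A guide more abundant in dim than in unsorted cells therefore marks a gene whose loss went with low GFP. Ratios are log2 of dim over unsorted, given as the mean ± SD of the 2 clones (n = 2).

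The table held 77441 guides. The dim libraries held 24261348 and 23976206 reads in clones 1 and 2, and the unsorted libraries held 39371569 and 30141241, so a guide had a median of 248, 232, 416 and 317 reads in that order. Guides with no read made up 4.44% and 13.0% of the dim libraries (95% Wilson intervals 4.30 to 4.59% and 12.8 to 13.2%), against 0.0981% and 0.139% of the unsorted libraries (0.0784 to 0.123% and 0.116 to 0.168%). The intervals cover counting error only. With 3 reads as the limit that a count of 0 allows, a guide without reads had less than 0.124 and 0.125 reads per 1000000 reads (RPM) in the dim libraries. The Gini index, which is 0 for an even library, was 0.444 and 0.508 in dim cells and 0.366 and 0.375 in unsorted cells, and 1% of the guides took 4.92 and 5.96% of dim reads against 3.55 and 3.66% of unsorted reads. These library-level differences are given as values without a test, 2 libraries against 2, where an exact permutation test cannot give a p below 0.333. In both dim libraries the most abundant guide targeted PA2G4.

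Guides against PA2G4, a ribosome-associated RNA-binding protein, were the most enriched in dim cells of all genes tested, with a log2 ratio of 4.98 ± 0.47 (31.5-fold). RBM33, an RNA-binding protein, followed at 4.67 ± 0.51 (25.5-fold), and PCBP2, a poly(C)-binding protein of the hnRNP family, at 3.79 ± 0.64. NXT1, the partner of the mRNA export receptor NXF1, reached 3.41 ± 0.32. CPSF6 and NUDT21, subunits of the cleavage factor that helps choose poly(A) sites, reached 3.38 ± 0.70 and 3.25 ± 0.41, and RPS25, a protein of the small ribosomal subunit, 3.14 ± 0.50.

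Across the 19107 genes tested, 60 were enriched in dim cells by alpha-robust rank aggregation over their guides (alpha-RRA, Benjamini-Hochberg adjusted p under 0.05), with log2 ratios from 0.67 to 4.98. All 60 had a positive ratio in both clones, and for 40 of them all 4 guides were up in both clones. The 15 genes at the smallest p that the random draws can give (2e-07, adjusted p = 0.000255) were the 7 above and TRMT112, ZC3HC1, CELF1, MORC2, TPR, EIF3B, EMG1 and NOB1. TRMT112, which activates several methyltransferases, and ZC3HC1, a protein of the nuclear pore basket, had ratios of 2.75 ± 0.46 and 2.75 ± 0.45. CELF1, which acts in splicing and mRNA decay, had 2.51 ± 0.65, and MORC2, an ATPase that works with the HUSH silencing complex, 2.41 ± 0.66. TPR, the scaffold of the nuclear basket, had 2.03 ± 0.16, and EIF3B, a subunit of translation initiation factor eIF3, 1.98 ± 0.62. EMG1, an 18S rRNA methyltransferase, had 1.64 ± 0.28, and NOB1, the nuclease that makes the 3' end of 18S rRNA, 1.46 ± 0.27.

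The next 10 genes by p held IWS1, a partner of the elongation factor SPT6 (2.41 ± 0.72), the basket nucleoporin NUP50 (2.16 ± 0.13), the splicing regulator PTBP1 (2.31 ± 0.36) and RTF1, a protein of the polymerase-associated PAF complex (1.98 ± 0.65). Ribosome synthesis was represented by the helicase DDX10 (1.78 ± 0.29) and by UTP14A (1.65 ± 0.36) and IMP3 (1.56 ± 0.16), which act in the processing of 18S rRNA, next to the ribosomal protein RPS20 (1.59 ± 0.32). The cell cycle gene RPRM (1.15 ± 0.02) and the deubiquitinase OTUD5 (1.07 ± 0.06) completed the 25. Adjusted p over these 10 genes ran from 0.000425 to 0.00183. Leaving out a dim library, so that a lone dim library remained, ended some of these calls. DDX10 and IMP3 were lost without that of clone 1, and UTP14A without that of clone 2. RPRM, RPS20 and OTUD5 were lost when either of them was left out. RPRM and RPS20 were lost with limma voom too.

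**Figure D1:**
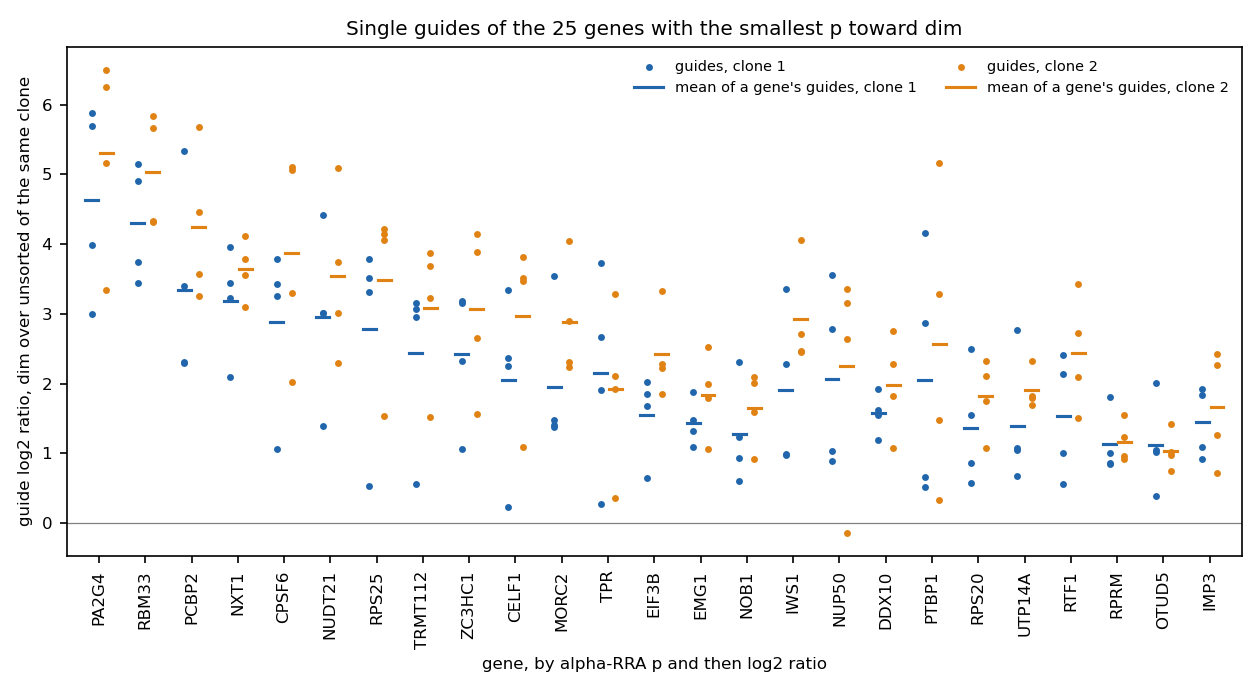
Log2 ratio of dim over unsorted for each guide (points) of the 25 genes with the smallest p toward dim, in clone 1 (blue) and clone 2 (orange), with the mean of a gene's guides as a bar. PA2G4 and RBM33 stand highest in both clones, with means of 4.64 and 4.31 in clone 1 and 5.31 and 5.04 in clone 2.

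In the hg38 annotation (GENCODE release 44), PA2G4 lies on chromosome 12 from 56104537 to 56113910 and PCBP2 on the same chromosome from 53452102 to 53481162, RBM33 on chromosome 7 from 155644451 to 155781485 and NXT1 on chromosome 20 from 23350791 to 23354771. CPSF6 lies on chromosome 12 from 69239569 to 69274358, NUDT21 on chromosome 16 from 56429133 to 56452199 and RPS25 on chromosome 11 from 119015712 to 119018691. Summed over its 4 guides, PA2G4 held 64062 and 84219 reads in dim cells of clones 1 and 2 against 2135 and 1482 in unsorted cells, or 2640 and 3513 against 54.2 and 49.2 RPM. For RBM33 the sums were 22659 and 33222 reads against 1309 and 956.

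The alpha-RRA p counts guides, not clones, as units. The gene-level limma test on the 4 libraries called 0 genes (smallest adjusted p = 0.0619, for PA2G4 and NXT1), with 349 genes up and 2346 down at an unadjusted p under 0.05. It tests against 0, while the median ratio of all genes was -0.22 and that of unchanged genes in simulated data -0.31. The larger number down is therefore not read as depletion of single genes. With clone as a paired replicate block, which leaves 1 residual degree of freedom, the gene-level test called 72 up and 68 down, 48 of the 60 among them. The same blocked fit gave 83 false calls among 18907 unchanged genes in simulated data. The count of 60 fell to 36 without the dim library of clone 1 (28 shared with the 60), to 36 with limma voom on the recovered reads (35 shared), which left CELF1, CPSF6 and TPR at adjusted p of 0.0643, 0.0675 and 0.112, and to 32 with a null drawn from non-targeting guides (32 shared), while NXT1 missed the threshold without the unsorted library of clone 2 (adjusted p = 0.103).

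Toward depletion from dim cells, where a guide would mark a gene whose loss went against low GFP, no gene passed by alpha-RRA. The simulation held no depleted genes, so the power to detect depletion is not known. The 3 genes with the smallest p were the zinc-finger gene ZNF618 at -1.38 ± 0.33 (adjusted p = 0.0764), C19orf52 (now TIMM29, of mitochondrial protein import; adjusted p = 0.0822), and NONO, a core paraspeckle protein, at -1.91 ± 0.54 (adjusted p = 0.289). For C19orf52 the 4 guides had 0 reads in both dim libraries, against 6.12 and 5.01 RPM summed over guides in unsorted cells, so its ratio is a limit set by the pseudocount. NONO had 12 reads in the dim library of clone 2. The 68 genes called down by gene-level limma with the clone block included NONO (adjusted p = 1.62e-05) and ZNF618 (adjusted p = 0.0227), from the fit with 83 false calls in simulated data. Alpha-RRA gave 0 depleted genes and 989 at an unadjusted p under 0.05, against 927 in the other direction. Both counts are close to what that threshold gives by chance over 19107 genes, so their difference carries no meaning. With the null drawn from non-targeting guides 10 genes passed toward depletion, but these guides were more abundant than targeting guides (median unsorted value 27.6 against 11.5) and spread less, so the null is not matched to the guides it tests. Their median ratio was also higher (-0.02 against -0.18), which would favour calls toward depletion and hold back calls toward dim. The count of 32 enriched genes under that null has the same limit. The median ratio of all genes was -0.22, and that of the 374 olfactory receptor genes, which these cells do not need, was -0.17, so ratios slightly below 0 were the rule. Non-targeting guides had medians of 0.02 and -0.01 in clones 1 and 2, with an SD over guides of 0.60 and 0.79, against 0.76 and 1.03 for targeting guides.

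The leading genes were partly the same in the 2 clones. Of the 100 genes with the highest ratio in each clone, 49 were shared, against 0.523 for independent lists. At the low end 3 of 100 were shared. Over all genes the ratios were weakly related (Pearson r = 0.179, Spearman rho = 0.114, across genes, which are not independent replicates). Among the 60 enriched genes, 50 had the higher ratio in clone 2. The rest, higher in clone 1, included YTHDC1, a nuclear reader of m6A (2.01 in clone 1, 1.26 in clone 2), and THOC1 (1.55 and 0.90). The correlation over all genes was 0.104 when guides were kept only at a mean of at least 50% of the median unsorted value.

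**Figure D2:**
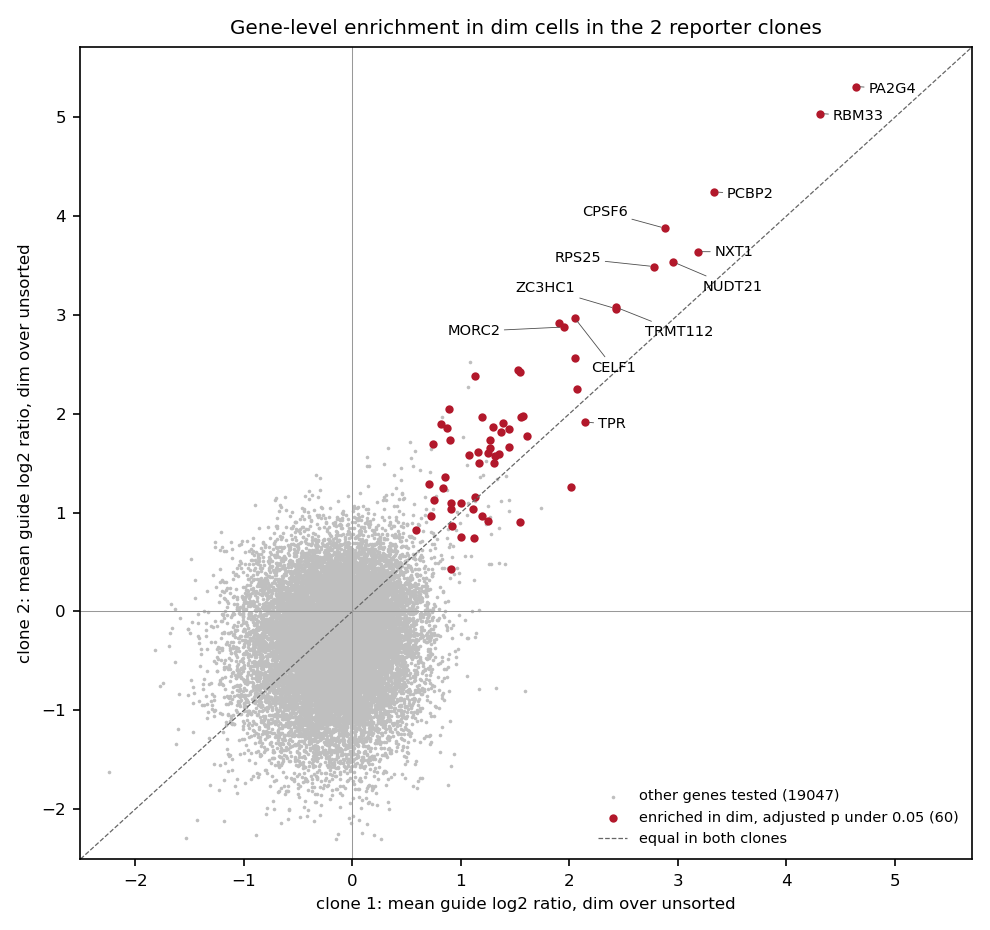
Mean guide log2 ratio of dim over unsorted for each gene in clone 1 (horizontal) and clone 2 (vertical), with the 60 enriched genes in red and all others in grey. The enriched genes lie in the upper right, mostly above the line of equal ratios, and PA2G4 and RBM33 are farthest out in both clones.

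The guides were next compared by 30 gene lists fixed before the data were examined, 7 of which shifted toward dim relative to all other genes by camera with its preset correlation. Nuclear pore genes shifted as a group, with 32 of 33 above the median of all genes and a median ratio of 0.43 (camera adjusted p = 1.3e-21, and adjusted p = 0.504 with an estimated correlation). Over all genes, 5 of the 33 were enriched, TPR and NUP50 with the ratios above, NDC1 at 0.94 ± 0.27, SEH1L at 1.69 ± 0.11, and NUP188, named after its value was seen, at 1.36 ± 0.77. Adjusted over the list alone, without correction for the number of lists, 16 passed.

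The NXF1-TREX list, the main route of mRNA export, had a median of 0.15 over 19 genes (camera adjusted p = 0.00160, and adjusted p = 0.504 with an estimated correlation). NXT1 and THOC1 (1.22 ± 0.46, adjusted p = 0.0467), of the THO complex, were enriched over all genes. Adjusted over the list alone, 6 were enriched, THOC6 (1.03 ± 0.57), of the same complex, among them, and 2 were depleted, the TREX proteins POLDIP3 (-0.98 ± 0.03) and CHTOP (-0.64 ± 0.09), the second named after its value was seen. NXF1 itself had 0.15 ± 0.86, with 0.76 in clone 1 and -0.46 in clone 2. ERH (-0.77 ± 0.07), DDX39A (0.42 ± 0.26), THOC7 (0.20 ± 0.74) and LUZP4 (-0.72 ± 0.02) did not pass either adjustment. The small SD of LUZP4 does not mean that its guides agreed. A guide had 0.53 in clone 1 and -1.51 in clone 2, and another had -2.34 and 0.05. In the TREX-2 list, a complex that links transcription to the pore, 0 of 6 genes were enriched over all genes and CETN3 (0.49 ± 0.34) over the list alone, with a median of 0.29 (camera adjusted p = 0.00481, and adjusted p = 0.504 with an estimated correlation).

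Exportins and Ran-cycle genes, which drive nuclear transport of proteins and some RNAs, held 0 of 18 enriched over all genes and 4 adjusted over the list alone, RAN (1.43 ± 0.16), RANBP1 (0.77 ± 0.03), RANGAP1 (0.72 ± 0.58) and NXF3 (0.61 ± 0.07). Despite the small SD of RANBP1, a guide of it had -0.59 in clone 1 and 1.07 in clone 2. XPO1, the exportin for leucine-rich signals, had a ratio of -0.28 in clone 1; in clone 2 its 3 guides had 0 reads in dim cells, against 3.19 RPM in unsorted cells, so no ratio is given there. The camera adjusted p of the list was 0.00740, and the adjusted p with an estimated correlation 0.504; its median was -0.0036 and its mean 0.08. Among 26 hnRNP and PTB genes, PCBP2 and PTBP1 were enriched over all genes, and HNRNPA2B1 (1.39 ± 0.81) adjusted over the list alone. The median of this list was -0.12 and its mean 0.18 (camera adjusted p = 0.0106 upward, and adjusted p = 0.594 with an estimated correlation).

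HUSH and heterochromatin genes, which silence transcription, had a median of 0.17 over 16 genes (camera adjusted p = 0.00145, and adjusted p = 0.504 with an estimated correlation). MORC2 was enriched over all genes. Adjusted over the list alone 5 passed, MORC2, the HUSH subunits MPHOSPH8 (0.80 ± 0.47), FAM208A (now TASOR, 1.67 ± 0.85) and PPHLN1 (1.05 ± 0.26), and the histone methyltransferase SETDB1 (0.52 ± 0.12), the last named after its value was seen. Cytosolic ribosomal protein genes had a median of 0.02 over 75 genes (camera adjusted p = 4.81e-09, and adjusted p = 0.973 with an estimated correlation), with 6 enriched over all genes and 14 adjusted over the list alone. All 6 encode proteins of the small subunit, RPS25 and RPS20 among them.

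**Figure D3:**
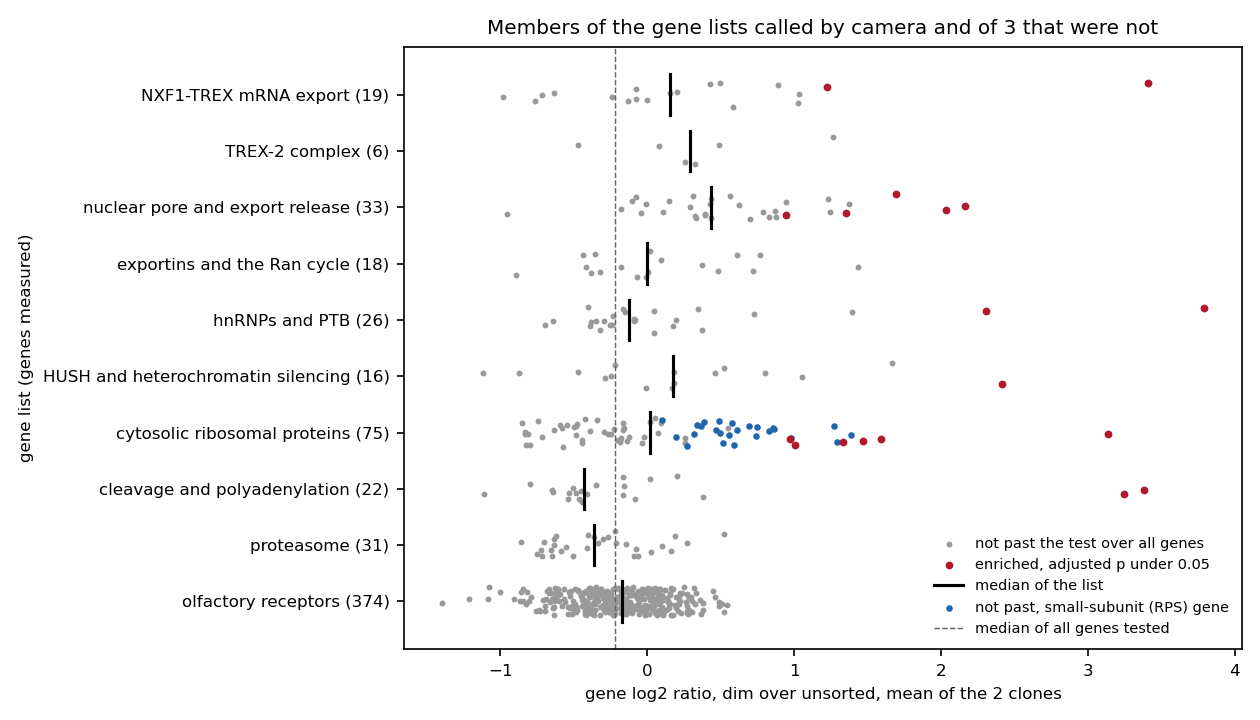
Log2 ratio of dim over unsorted, mean of the 2 clones, for each gene of the 7 lists called by camera and of 3 lists that were not, with enriched genes in red, list medians as black bars and the median of all genes (-0.22) as a dashed line. Small-subunit ribosomal proteins that did not pass are blue, and the nuclear pore list has 32 of 33 genes to the right of the dashed line.

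In the other 23 lists the camera adjusted p was 0.253 or more. CPSF6 and NUDT21 were the only 2 of 22 cleavage and polyadenylation genes to pass over all genes or over the list alone, and the list's median was -0.43. In further lists SRSF11, an SR-like splicing protein (1.44 ± 0.18), YTHDC1 (1.63 ± 0.54), the decapping scaffold EDC4 (0.84 ± 0.17), RTF1 and EIF3B were enriched over all genes. Adjusted over the list alone, the importins TNPO1 (0.76 ± 0.00) and KPNA2 (0.32 ± 0.18), the splicing factor SRSF1 (0.88 ± 0.70) and the decay helicase DDX6 (1.19 ± 0.65) were enriched too. Over all genes their alpha-RRA adjusted p ran from 0.0753 (TNPO1) to 0.431 (SRSF1), and a KPNA2 guide stood at -2.26. Despite the small SD of TNPO1, a guide of it had 0.94 in clone 1 and -0.71 in clone 2. Depletion adjusted over the list alone was found for the Integrator genes INTS1 (-1.04 ± 0.16) and INTS6 (-1.22 ± 0.10) and for the growth kinases MTOR (-1.09 ± 0.07) and AKT1 (-0.59 ± 0.35). It was also found for the paraspeckle list's NONO and MATR3 (-0.58 ± 0.44). TAF6 of TFIID passed likewise (-0.76 in clone 1, and 0 reads in dim cells of clone 2 against 12.9 RPM in unsorted cells). Over all genes the alpha-RRA adjusted p of these depleted genes ran from 0.289 (NONO) to 0.851 (MATR3). For MATR3 2 of 4 guides were down in both clones. No gene passed over all genes or over the list alone among 31 proteasome, 54 core spliceosome, 35 respiratory chain, 28 Mediator, 18 RNA exosome, 18 SWI/SNF, 12 RNA polymerase II, 9 exon junction and 5 cap-binding genes.

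The list of NORAD partners and PUMILIO proteins also held genes of the cohesin complex, SMC1A, SMC3 and RAD21 among them. Its 9 genes had a median of -0.30, and none passed either adjustment. PUM2, which NORAD binds in the cytoplasm, had -0.30 ± 0.81, and RBMX, a nuclear RNA-binding partner, -0.63 ± 1.43.

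None of the 7 list calls held with an estimated correlation or with fry. The estimated-correlation test rests on the 2 residual degrees of freedom of the 4 libraries, so its adjusted p cannot decide against a shift. For TREX-2 the estimated correlation (-0.125) was below the preset one, yet the unadjusted camera p rose from 0.000801 to 0.0753. For the nuclear pore and ribosomal protein lists the estimated correlation was 0.210 and 0.371, far above the preset 0.01. Their camera adjusted p at the preset correlation, 1.3e-21 and 4.81e-09, overstate the evidence if genes move together to that extent. Fry tests a list against no change, not against all other genes, so it does not test the same shift. Among 10000 random lists matched on unsorted value, the median of the hnRNP list stood at percentile 88.3 and that of the exportins at 98.6. The other called lists stood at 99.89 or above. The olfactory receptor control list stood at 98.8, so a percentile of that size does not set a list apart from a neutral one. Without the dim library of clone 1 the adjusted p was 0.0965 for TREX-2, 0.0965 for the exportins and 0.0618 for the hnRNPs, and with the median in place of the mean over a gene's guides it was 0.101 for the exportins and 0.166 for the hnRNPs.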

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

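Of the alternatives in this part, the pseudocount of 0 and limma voom were chosen after the data were seen. The planned count tests, edgeR and DESeq2, were not run. Rescaling every library to the same total moved no call because the totals were already equal. The count of enriched genes was 60, and it was 51 to 77 in the alternatives on pseudocount, filter, scaling, clone block (66, 52 shared) and guide ranking. It was 36 with voom, 32 with a null from non-targeting guides and 102 at an adjusted p under 0.25. Leaving out 1 library at a time gave 36 to 59 enriched and 0 to 1 depleted genes. Depleted genes numbered 2 with a pseudocount at 1% of the median or of 0, 1 without a filter, 1 with voom, 1 when guides were ranked by mean log2 ratio, 10 with the non-targeting null and 2 at an adjusted p under 0.25. Gene-level limma called 2 genes with centring on non-targeting guides, 2 with the median over guides, 4 with voom and 140 with the replicate block. Single guides past limma numbered 0 (8828 at an unadjusted p under 0.05), 2 with the filter at 50% of the median, 171 with the replicate block and 1546 at an adjusted p under 0.25. Leaving out 1 library gave 17 to 14278 genes by gene-level limma and 0 to 55953 guides. The highest values came without a dim library, where the lone dim library is assumed to vary like the unsorted ones. List calls were 7, or 0 with an estimated correlation, 0 with fry and 4 to 10 with 1 library left out, and the paired block ended none of the 7 (8 lists passed) and none of the 25 named genes. The clone correlation was 0.215 with a pseudocount at 50% of the median and 0.104 with the stricter filter. Unless a sentence says otherwise, the cause was not tested.

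Of the 25 named genes, 15 stayed past the threshold in all 17 alternatives. OTUD5, RPRM and RPS20 missed it when either dim library was left out, and RPRM and RPS20 also with voom. DDX10 and IMP3 missed it without dim 1 (0.0791 and 0.283), UTP14A without dim 2 (0.123), NXT1 without unsorted 2 (0.103), and CELF1, CPSF6 and TPR with voom. No named gene past the test reversed direction. In the simulation 14.9% of 2-fold increases were called, so increases of that size were often not detectable with these sorted cell numbers. All guides of a gene changed alike there, so real genes may be called less often. Depletion was not simulated.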

Other observations

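The test of counting noise was chosen after its result was seen, the lists of 40S and 60S assembly after the gene results were seen, and the ranges over settings after the differences were seen. Beyond the 25 named genes, many of the 60 enriched genes act in making the small ribosomal subunit. These genes were chosen after their values were seen. WBSCR22 (now BUD23), the 18S rRNA methyltransferase that TRMT112 activates, had 1.43 ± 0.25, the late-maturation kinase RIOK1 1.40 ± 0.14, the GTPase BMS1 1.05 ± 0.06, and TSR2, a chaperone of RPS26, 1.08 ± 0.17. FAU, which encodes the small-subunit protein eS30, had 1.08 ± 0.24. A list of 62 genes of 40S assembly held 20 of the 60 and had a median of 0.99 (camera p = 0.0425 with an estimated correlation of 0.247, and fry p = 0.0169, neither adjusted, with the leading genes included), and a list of 51 genes of 60S assembly had a median of -0.30 with 0 enriched. Small-subunit (RPS) genes had a median of 0.70 over 31 genes, of which 30 were positive in both clones, and large-subunit (RPL) genes -0.32 over 44 genes, of which 4 were positive in both clones. Among enriched genes outside any list were SRP14 of the signal recognition particle (1.32 ± 0.59), FZR1, an activator of the anaphase-promoting complex (1.00 ± 0.41), the ubiquitin ligase TRIP12 (0.88 ± 0.17) and PCIF1, which methylates the first nucleotide after the mRNA cap (0.70 ± 0.17).

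The enrichment of 40S assembly genes was tested on the 46 list members outside the leading genes by ratio or p, whose median was 0.74, though the list was made after the gene results and 6 of the 46 are among the 60 enriched genes. Low guide abundance was argued against, since this median stood at percentile 100 of 10000 random lists matched on unsorted value. The olfactory receptor control list stood at percentile 98.8, though its median of -0.17 was close to that of all genes (-0.22). A general effect of losing an essential gene was argued against by a median 1.10 higher than that of the proteasome genes. This holds only as far as the proteasome stands for essential genes, and its own effect on GFP was not tested. Loss of either subunit alike was argued against by a median 1.04 higher than that of 60S assembly. The 28 RPS genes outside the leading genes, 3 of them enriched, argued against it too, at 0.92 above RPL genes. Each difference had a permutation p of 2e-05, the smallest that 100000 permutations can give in a two-sided test. That p treats genes as independent and so overstates the evidence where genes of a list move together. With the leading RPS genes included, the last difference was 1.01 and ran from 0.61 to 1.41 across 15 settings, and that between the assembly lists ran from 0.69 to 1.30. Whether GFP made from the IRES depends on the supply of 40S subunits was not tested and would need a reporter whose GFP is translated without the IRES, so an effect on export or stability of the NORAD transcript remains open as well. The same question is open for the other enriched genes, PA2G4 and PCBP2 among them. All libraries came from this reporter, so an effect on the IRES cannot be told from one on the NORAD transcript.

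Non-targeting guides spread widely between dim and unsorted cells, with an SD of 0.60 and 0.79 in clones 1 and 2 where read counting alone gives 0.0734 and 0.0769. Counting noise was argued against by variances 67.7 and 106 times as high as counting gives. A small number of sorted cells per guide may account for part of the spread: the rarer guides had 2.30 and 2.15 times the variance of the more abundant ones. The spread corresponds to 216387 and 156678 cells, or 2.79 and 2.02 per guide, beside the stated 200000 or more. In clone 2 it thus exceeds what the stated number gives. Noise from amplifying little DNA would fall with abundance too and was not separated from cell number. Over the non-targeting guides the ratios of the 2 clones correlated at 0.200, against 0.103 for targeting guides. Sampling cells separately in each clone was not shown to give such a shared part. No biological explanation was tested for this spread.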
